A study of Homo sapiens with 3 samples.

How the data were processed

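CAGE libraries had been made from total RNA of EBC-1 cells, 1 library each for a control siRNA and 2 RAB11A siRNAs, with 600 pmol siRNA per electroporation. The labels give a time of 72 h after plating for every library. Per their protocols, RNA was purified on columns, and first-strand cDNA was extended to the capped 5′ end and joined to barcode tags. The authors deposited a table of CPM per gene and strand, with 1 column per library, and every column was matched to its library by name. The submitters' processing notes name the build hg19 and the tools BWA and HISAT2. Their roles and versions, the counting tool, the annotation release and the handling of reads with several matches are not given in the sources used here. Every gene in the table reached at least 0.52 CPM in 1 library, so genes below about 0.5 CPM throughout are not listed.

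Deposited CPM values were whole multiples of 0.04 for 100.0% of values in each library, within a tolerance of 0.005 CPM, and whole tag counts were recovered from these deposited values. The step gave about 24999950 tags in all 3 libraries. How equal totals arose is not given in the sources used here. Tags summed over genes came to 25174787, 25204585 and 25137457 for control, siRNA 1 and siRNA 2, slightly above the totals, and the cause was not tested. Among genes with a mean of at least 5 CPM, 837 had values identical to those of another gene, in 406 distinct sets. A gene at 5 CPM rests on 125 tags, and the median counting standard error of a log2 ratio to control was 0.071. A value of 0 tags allows up to 0.12 CPM by the limit of 3 tags, for counting error only.

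The main measure was the log2 ratio of (CPM + 1) between libraries, over genes with a mean of at least 5 CPM, and genes at least 2-fold apart on that scale were counted. A pseudocount of 1 CPM understates the ratio of low genes. Counting standard errors came from the Poisson variance of the tags. No p-value across genes is given as a main result, because each group has 1 library. The design, the alternatives, 27 gene lists and the rule for named genes were set before the data were examined. That rule took RAB11A and its relatives, up to 12 genes per direction at least 2-fold from control in both siRNA libraries, the 5 highest and 5 lowest of each pair of libraries, all with a mean of at least 10 CPM, and up to 4 members of each list. Other genes were named after their values were seen: ACTA1, TRIM16L, KIF20A, HSPA5, DHRSX, ZBED1 and genes in the closing section. For each list with at least 3 measured members the median was placed among 10000 random lists of the same size drawn from 20 expression bins.

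The recovered tags were also compared between pairs of libraries with an exact two-sided binomial test and Benjamini-Hochberg adjustment, which compares these libraries, not the conditions. At an adjusted p of 0.05 it called 2518 genes higher and 3143 lower with siRNA 1 than control, 1983 and 3230 with siRNA 2, and 2312 and 1656 between siRNA 1 and siRNA 2. On simulated tags with known changes in 200 of 10788 genes, the 2-fold count for siRNA 1 against control found all 50 genes changed 2.5-fold, all 50 changed 4-fold and all 50 changed 8-fold. It found none of the 50 genes changed 1.5-fold and called 0 of 10588 unchanged genes, of which the binomial test called 8. These simulated tags carried counting error only, so the 0 says nothing of spread between cultures. Of simulated lists of 20 genes, 4% of unshifted ones and 95% of those shifted by 0.3 lay outside the matched range. These lists held random genes with independent normal values, so the 4% does not carry over to lists whose genes vary together.

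Sequence checks used the GRCh37 genome with the GENCODE annotation lifted to it, where 13163 of 13479 gene identifiers (97.7%) were found. The first 50 bases of every annotated transcript start were searched against the genome with minimap2 2.31 in its short-read mode. A gene counted as having a copy if any of its annotated starts matched another place with 2 or fewer mismatches. That held for 1861 genes, and other starts of such a gene may have no copy. Genes whose identifier was not found were not searched, among them RBM8A. Seed sites were exact matches in canonical 3′ UTRs to the 7 bases that pair with guide positions 2 to 8, the given sequences being read as sense strands. Other scalings were TMM from edgeR 4.0.16 and median ratios, and limma 3.58.1 in R 4.3.3 was run with both siRNA libraries as 1 group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1, did the remaining work. The alternatives tried were pseudocounts of 0.5 and 5 CPM, minimum means of 1 and 20 CPM, no filter, both scalings, the binomial test and limma. Counting identical genes once and leaving out genes with copies were added after seeing the data.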

Results

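RNA 5′ ends were counted by cap analysis of gene expression (CAGE), which sequences tags from the capped start of transcripts, in EBC-1, an established human lung squamous cell carcinoma line. Cells had been electroporated with a negative control siRNA or with 1 of 2 siRNAs against RAB11A, a small GTPase of the recycling endosome. The 3 libraries formed 3 groups of 1 library each, so no difference below has a replicate check. The deposited values were tags per gene in CPM, tags scaled to a fixed library total, for 13479 genes. Their spacing of 0.04 CPM per tag gave about 24999950 tags in every library. A total of 10788 genes had a mean of at least 5 CPM, equal to 125 tags, and were compared on the log2(CPM + 1) scale. Standard errors and intervals treat tags as independent counts and cover counting error only. Whether each tag stands for a separate molecule is not given in the sources used here.

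The first question was how far each siRNA lowered its target. RAB11A (ENSG00000103769, chr15:66018392-66184327, plus strand, GRCh37/hg19) stood at 135 CPM in the control library (3383 tags, 95% Poisson interval 130.8 to 140.0 CPM). It stood at 7.48 CPM with siRNA 1 (187 tags, 6.45 to 8.63) and at 22.7 CPM with siRNA 2 (567 tags, 20.9 to 24.6). The level remaining was 5.53% of control with siRNA 1 (95% exact interval 4.75% to 6.41%) and 16.8% with siRNA 2 (15.3% to 18.3%). The log2 ratios were -4.01 with a counting standard error of 0.096 and -2.53 with 0.063. The ratio of siRNA 1 to siRNA 2 was -1.48 with a counting standard error of 0.11. RAB11B, the closest relative of RAB11A, stood at 123.6, 113 and 97.4 CPM with control, siRNA 1 and siRNA 2, or log2 ratios of -0.12 and -0.34. RAB25, the epithelial member of the family, was looked up but matched no gene symbol in the values used here, so no level is given.

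The siRNA 1 sequence, GCAUCCAGGUUGAUGGAAA, matched the canonical RAB11A transcript over 19 bases at chr15:66169784-66169802 (GRCh37), inside coding exon 2 of 5. The siRNA 2 sequence, AGCAAGAGCUUUUGCAGAA, matched across the junction of coding exons 3 and 4, with 17 bases ending at chr15:66170293 and 2 bases starting at chr15:66172009. Neither sequence had an exact match in the canonical transcript of another listed gene. Both sites lie 3′ of the transcript start that CAGE counts.

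**Figure D1:**
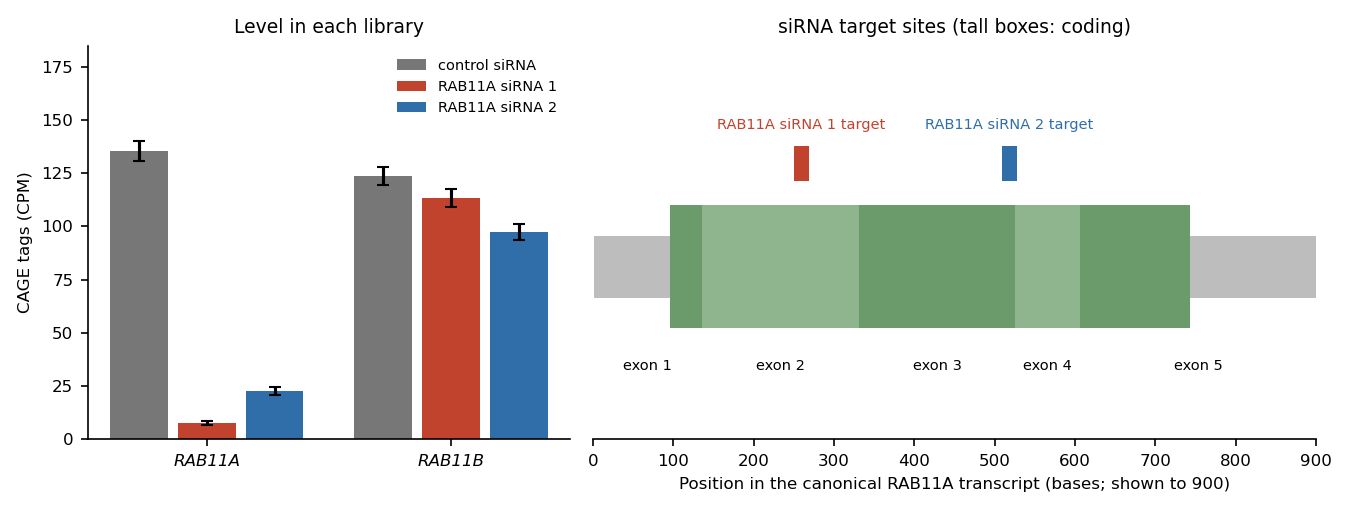
Left, CAGE level of RAB11A and RAB11B in CPM in the 3 libraries, with bars for the single library of each group and whiskers for the 95% Poisson interval of the tags. Right, position in bases of both siRNA target sites on the canonical RAB11A transcript, with coding parts as tall boxes and exons in alternating shades. RAB11A stood at 135 CPM with control, 7.48 with siRNA 1 and 22.7 with siRNA 2, and both targets lie in the coding sequence.

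With siRNA 1, 40 genes were at least 2-fold higher and 56 at least 2-fold lower than in the control library. Besides RAB11A, the lower genes included GDF15, a stress-induced cytokine, at 53.2 against 8.04 CPM (log2 ratio -2.58, counting standard error 0.098). LAMP3, a lysosome-associated membrane glycoprotein, had a ratio of -1.56, and HMOX1, the inducible heme oxygenase, -1.54. EPAS1, a hypoxia-inducible transcription factor, had -1.49. SERPINB2, a plasminogen activator inhibitor, was higher, at 7.76 against 31.8 CPM (1.90, counting standard error 0.104). Many of the larger ratios belonged to loci with near-identical copies or with no copy search. SNORD3B-1, a U3 small nucleolar RNA gene, stood at 0.96 against 298.7 CPM, and AC013268.5, a long noncoding RNA, at 1.64 against 23.0. DHRSX and ZBED1, overlapping pseudoautosomal genes with identical values, stood at 21.4 CPM with siRNA 1 and at 0 in the other libraries. RBM8A, a core exon junction complex gene that could not be searched for copies, stood at 353 against 11.3 CPM. Without the genes that had copies or could not be searched, an alternative added after seeing the data, the counts were 21 higher and 41 lower. The higher ones still include DHRSX and ZBED1, for which the search found no copy although they are pseudoautosomal.

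With siRNA 2, 21 genes were at least 2-fold higher and 29 at least 2-fold lower than control. GDF15 stood at 16.6 CPM (log2 ratio -1.63, counting standard error 0.077), EPAS1 at -1.28, HMOX1 at -1.27 and UPP1, a uridine phosphorylase, at -1.16. SERPINB2 was 1.26 above control (counting standard error 0.11). Among genes with a mean of at least 10 CPM, the most extreme values belonged to RBM8A, at 11.1 CPM, and to loci with copies, pseudogenes or a pseudoautosomal gene. XAGE1C, a cancer/testis antigen gene on the X chromosome, stood at 124 CPM in control, 80.4 with siRNA 1 and 0.40 with siRNA 2. DDT, D-dopachrome tautomerase, stood at 0.16, 4.72 and 55.4 CPM. BOLA2 and BOLA2B, which carry identical values, stood at 20.3, 19.3 and 0.28 CPM. VAMP7, a vesicle SNARE gene of the pseudoautosomal region, stood at 0.12, 0.12 and 39.0 CPM, and RP11-48B14.1, annotated as a processed pseudogene, at 0.12, 0.20 and 68.6. DHFRP1, a processed pseudogene of dihydrofolate reductase, stood at 0.04, 0.24 and 30.8 CPM, and SNORD3C at 0.64, 0.72 and 37.3. Without genes that had copies or could not be searched, the counts were 7 higher and 16 lower. The higher ones still include the pseudoautosomal VAMP7 and the pseudogene RP11-48B14.1, for which the search found no copy.

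Both siRNA libraries shared 17 genes at least 2-fold lower than control and 11 at least 2-fold higher. The lower genes with no copy found were RAB11A, GDF15, EPAS1, HMOX1, UPP1, a TRIM16 entry, MKNK2, LAMP3 and RAB43. Also among them were MIR3189, whose values are identical to those of GDF15, and ACTA1, skeletal muscle actin. ACTA1 stood at 13.2, 1.20 and 2.44 CPM in control, siRNA 1 and siRNA 2, and was named after its values were seen because it lies outside the naming rule. UPP1 had the highest level of the lower genes with no copy found, at 451, 169.6 and 200.6 CPM. MKNK2, a kinase that phosphorylates a cap-binding initiation factor, stood at 269, 123 and 126 CPM. RAB43, a Golgi-associated GTPase gene, stood at 34.8, 15.6 and 16.4. The TRIM16 entry (ENSG00000251537) stood at 18.2, 7.64 and 7.44 CPM, while its relative TRIM16L stood at 2.08, 10.5 and 13.4. The GENCODE annotation used here gives that TRIM16 identifier no gene name. The sum over the 3 TRIM16 and TRIM16L entries was 27.0, 23.8 and 26.2 CPM, so the lower ratio describes that entry alone.

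The higher genes with no copy found were SERPINB2 and S100A4, a calcium-binding protein of motile cells, at 250.4, 502 and 508 CPM (log2 ratios 1.00 and 1.02, counting standard error 0.022 for each). DNAJB6, a heat shock cochaperone with an annotated start that matches elsewhere in the genome, stood at 70.5, 198.6 and 253 CPM. Whether its tags came from such a start was not tested. RP6-206I17.1 stood at 5.64, 19.7 and 16.2 CPM. LINC00152, a long noncoding RNA, stood at 32.9, 3.96 and 3.24 CPM, and AC068491.1, its near-copy on the same chromosome, at 2.52, 9.28 and 42.5. Without genes that had copies or could not be searched, 2 genes were higher and 11 lower in both libraries.

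Across the 10788 genes the log2 ratios of siRNA 1 and siRNA 2 to control had a Pearson correlation of 0.64 and a Spearman correlation of 0.70. Genes are not independent replicates, and both ratios share the control library. In 100 simulations of unchanged libraries with a shared control and the spread seen between both siRNA libraries, the correlation averaged 0.499 and reached 0.585. The observed covariance was 0.0675 against a simulated 0.0382. Simulated overlaps averaged 12.4 genes higher and 11.7 lower and reached 23 and 19, so the observed 11 and 17 lay within them. Independent lists would share 0.08 and 0.15 genes. Without genes that had copies or could not be searched, the correlation was 0.668 against a simulated 0.499 and the covariance 0.0520 against 0.0264. The 11 shared lower genes exceeded the simulated maximum of 7, while the 2 shared higher genes lay below the simulated mean of 3.35. The 11 include RAB11A, the target of both siRNAs, and MIR3189, whose values are those of GDF15. They also include the TRIM16 entry, whose relative TRIM16L moved the other way. The simulations had no target gene and drew genes independently, so 11 against 7 overstates the excess. The simulations gave the control library the same spread as the siRNA libraries. The single control library could not be split, so part or all of any excess may come from the shared control.

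**Figure D2:**
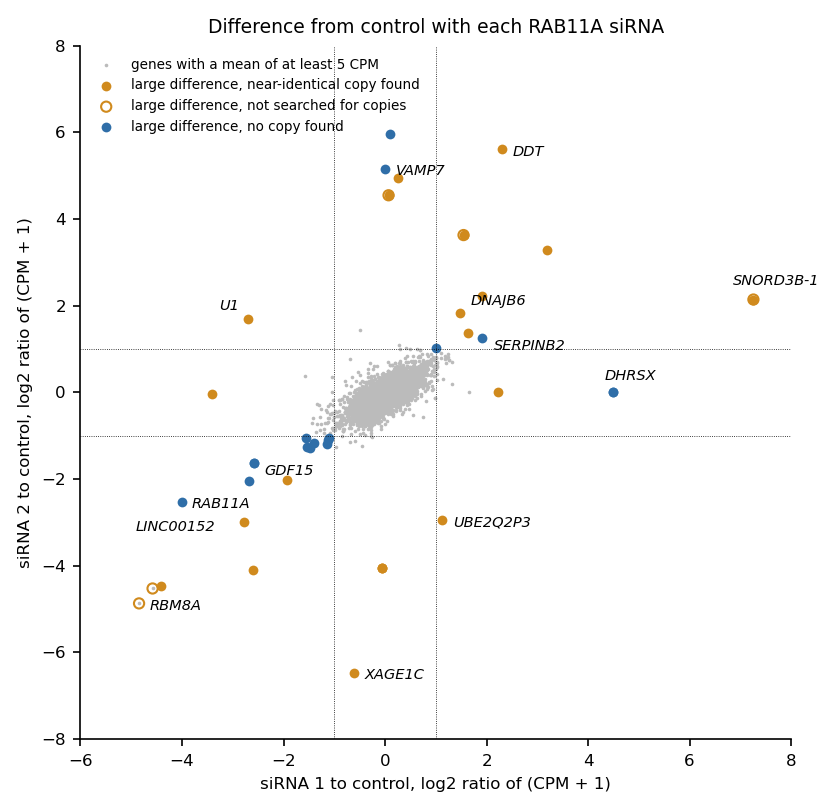
Each point is a gene, with the log2 ratio of (CPM + 1) to control with siRNA 1 on the horizontal axis and with siRNA 2 on the vertical axis, from 1 library per group. Dotted lines mark 2-fold. Coloured points are the genes at least 4-fold apart in any pair of libraries or at least 2-fold apart from control in the same direction in both. RAB11A (-4.01 and -2.53) and GDF15 (-2.58 and -1.63) lie at the lower left, and most genes far from the diagonal have near-identical copies.

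Lists of histone, DNA replication, mitosis, YAP/TAZ target and cholesterol genes had medians above control in both siRNA libraries. All 15 measured replication-dependent histone genes were above control in both, with median log2 ratios of 0.66 with siRNA 1 and 0.47 with siRNA 2. HIST1H1B, a linker histone gene, stood at 907, 1821 and 1484 CPM. The 38 measured G1/S and DNA replication genes had medians of 0.44 and 0.28, with 33 above control in both. Among them RRM2, the small subunit of ribonucleotide reductase, had ratios of 0.91 and 0.69, and TYMS, thymidylate synthase, 0.70 and 0.48. The 34 G2/M and mitosis genes had medians of 0.52 and 0.10, with 24 above control in both and 10 below control with siRNA 2. MKI67, the Ki-67 proliferation marker, had ratios of 0.69 and 0.54, and CDK1, the mitotic kinase, 0.77 and 0.45. YAP/TAZ targets had medians of 0.35 and 0.26, with 15 of 19 above control in both. CYR61, a matricellular protein, stood at 240.5, 487 and 388 CPM, and ANKRD1 had ratios of 0.81 and 0.54. Cholesterol biosynthesis and uptake genes had medians of 0.24 and 0.26, with 22 of 27 above control in both, among them FDPS at 0.47 and 0.49. SREBF1, a sterol-regulated transcription factor, was lower, at -0.75 and -0.47. The medians of these 5 lists lay above the middle 95% of 10000 random lists matched on expression in both libraries. The lowest percentile was 99.97, for G2/M with siRNA 2. Here and below, both ratios use the same single control library, so the siRNAs are not independent checks. Genes of a list can vary together, which the random lists do not model. Of 26 lists, 10 lay outside the range with siRNA 1, 10 with siRNA 2 and also 10 between the siRNAs. Among all genes, 31.4% were above control in both libraries and 44.5% below in both.

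Lists of unfolded protein response and ATF4 genes and of lysosome genes had medians below control in both siRNA libraries. So did p53 targets, whose place with siRNA 2 depended on the filter. Of the 23 measured unfolded protein response and ATF4 targets, 20 were below control in both libraries, with medians of -0.41 and -0.34, below all matched lists. DDIT3, a proapoptotic stress transcription factor, had ratios of -1.02 and -0.82, and TRIB3, a pseudokinase induced by ATF4, -1.28 and -0.86. DDIT4, an inhibitor of mTORC1, had -0.98 and -0.82. HSPA5, the endoplasmic reticulum chaperone BiP, stood at 1393, 744 and 781 CPM. The 19 p53 targets had medians of -0.29 and -0.21, at percentiles 0.01 and 1.03, and included GDF15 and SESN2, of which SESN2 is also in the ATF4 list. With siRNA 2 the p53 median lay inside the matched range at a minimum mean of 1 CPM (-0.07, percentile 33.5), with no filter (-0.07, 35.7), at 20 CPM (-0.18, 4.38) and with a pseudocount of 5 CPM (-0.14, 5.43). TP53INP1 had ratios of -0.83 and -0.86, and XPC, a DNA damage sensor, -0.55 and -0.72. The 24 lysosome and autophagy genes had medians of -0.16 and -0.22, at percentiles 0.60 and 0.01. Of these, WIPI1 had ratios of -1.01 and -0.49, MAP1LC3B -0.71 and -0.49, and CTSD, the protease cathepsin D, -0.61 and -0.33.

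For 4 lists the median lay outside the matched range in 1 library. NRF2 targets had a median of -0.51 with siRNA 1, below all matched lists, and -0.07 with siRNA 2, at percentile 22.2. FTH1, ferritin heavy chain, stood at 2248, 845 and 1488 CPM, and FTL, ferritin light chain, at 3796, 1909 and 2804, while OSGIN1 had ratios of -0.78 and -0.73. Beta-catenin targets, with 8 genes measured, had medians of 0.26 (percentile 99.6) and 0.02, and DKK1, a secreted Wnt inhibitor, had ratios of 0.97 and 0.75. NF-kB and inflammatory genes had medians of -0.03 and -0.22 (percentile 0.92), with CXCL5 at -0.97 and -0.70 and BIRC3 at 1.00 and 0.54. The NF-kB median with siRNA 2 was -0.21 at percentile 2.86, inside the matched range, without genes that had copies or could not be searched, and -0.21 at percentile 3.98 with a minimum mean of 20 CPM. Heat shock and electroporation stress genes had medians of 0.01 and 0.18 (percentile 99.9), with HSPB1 at 0.46 and 0.34 and HSPE1 at 0.37 and 0.42, and the median with siRNA 1 was -0.07 without genes that had copies or could not be searched.

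Medians of the other lists with at least 3 measured members lay inside the range of matched lists in both libraries. The 32 RAB11 recycling endosome genes had medians of -0.05 and -0.04, and none was 2-fold from control. The largest difference there was in RAB4B, at 8.52, 4.32 and 5.48 CPM. The median with siRNA 2 was 0.01 under other scalings, which shift every ratio to control by up to 0.05, so medians this close to 0 carry no direction. Receptor tyrosine kinases and ligands had medians of -0.13 and -0.16, including VEGFA at -1.11 and -0.60 and EGFR at 0.48 and 0.23. Without genes that had copies or could not be searched, 11 of these kinase and ligand genes were left, and their median with siRNA 1 was -0.25, below the matched range (percentile 0.60). With siRNA 2 the kinase and ligand median was 0.05 at a minimum mean of 20 CPM and 0.03 with no filter. The median of 17 apoptosis regulators with siRNA 1 was 0.12 without genes that had copies or could not be searched, above the matched range (98.58). ERK pathway output had -0.07 and -0.11, apoptosis regulators 0.04 and 0.02, interferon response -0.07 and -0.02, and hypoxia and glycolysis 0.02 and 0.01. The interferon median with siRNA 1 was 0.08 at minimum means of 1 and 20 CPM, and with siRNA 2 it was 0.03 under both other scalings, so it carries no direction. Epithelial junctions had -0.04 and -0.07, integrins and basement membrane 0.10 and -0.07, and TGF-beta response 0.15 and -0.06. Mesenchymal transition genes had medians of -0.08 and 0.02 and means of 0.06 and 0.16. S100A4 and TAGLN, an actin-binding protein, were higher, with TAGLN at 1.21 and 0.66. VIM was lower, at -0.37 and -0.28, as was LOX, at -0.435 and -0.174. Of the 12 measured, 4 were above control in both libraries and 4 below in both. Ribosomal protein genes had medians of -0.07 and -0.01, nuclear-encoded respiratory chain genes 0.00 and 0.02, and the small RNA pathway -0.18 and -0.09. The ribosomal medians were -0.01 and 0.01 over 21 genes and the respiratory chain medians -0.05 and -0.01 over 23 without genes that had copies or could not be searched. The mean of the ribosomal list with siRNA 2 was 0.01. Of 37 squamous lineage genes only 3 were measured, SFN, PERP and S100A2, with medians of 0.02 and -0.02 and a mean of 0.03 with siRNA 2. Of 20 markers of fibroblasts, endothelium, leukocytes and alveolar cells, none was among the genes compared.

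**Figure D3:**
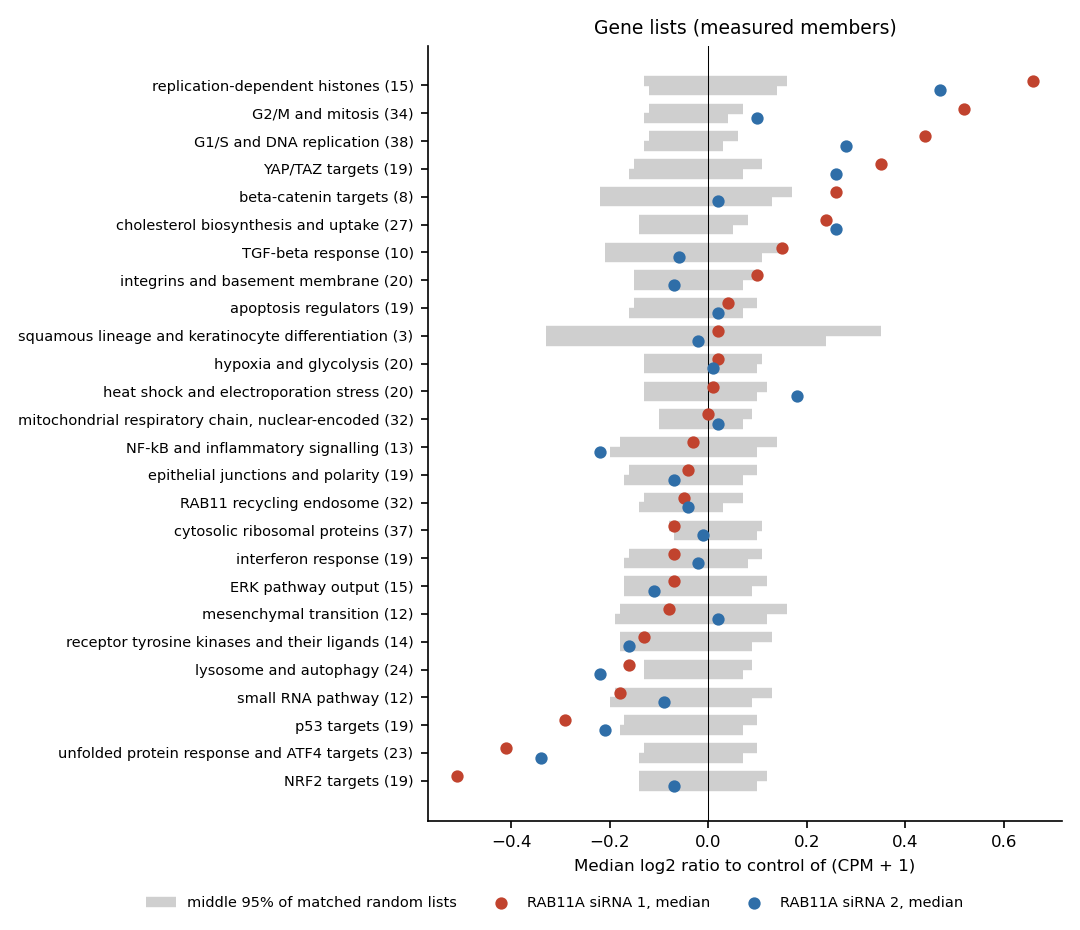
Median log2 ratio of (CPM + 1) to control for each gene list, as points for siRNA 1 (red) and siRNA 2 (blue) from 1 library per group, with the number of measured members in parentheses. Grey bars span the middle 95% of 10000 random lists matched on expression. Histone, cell cycle, YAP/TAZ and cholesterol lists lie to the right of the bars for both siRNAs. The unfolded protein response and ATF4, p53 and lysosome lists lie to the left for both. NRF2 targets lie to the left for siRNA 1 alone (-0.51 against -0.07).

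A comparison of both siRNA libraries with each other does not use the control. Mitotic genes were higher with siRNA 1, with a median log2 ratio of 0.41 to siRNA 2 for the G2/M list, above all matched lists. KIF20A, a mitotic kinesin, stood at 62.6 CPM with siRNA 1 and 33.9 with siRNA 2. The G1/S list had a median of 0.19 and histones 0.16, while NRF2 targets had -0.27 and unfolded protein response and ATF4 targets -0.12. Integrins and basement membrane genes had 0.15 (percentile 99.88), with COL4A2, a basement membrane collagen, at 103 against 59.8 CPM, but 0.07 inside the matched range at a minimum mean of 1 CPM (88.4) and with no filter (89.3). NF-kB and inflammatory genes had 0.18 (percentile 99.27), lysosome and autophagy genes -0.09 (0.46), ribosomal protein genes -0.08 (1.01) and the small RNA pathway -0.09 (2.32). Medians of the other lists lay inside the matched range in this comparison. Without genes that had copies or could not be searched, the ribosomal median of -0.05 (14.11), which was also inside at a minimum mean of 20 CPM (2.65), and the small RNA pathway median of -0.09 (3.54) lay inside it and the YAP/TAZ median of 0.11 (97.82) above it. Of single genes, 18 were at least 2-fold higher and 20 at least 2-fold lower with siRNA 1 than with siRNA 2. Among genes with a mean of at least 10 CPM, the largest on the higher side were XAGE1C, SNORD3B-1, and BOLA2 and BOLA2B, whose values RP11-231C14.3 shares. RP11-48B14.1, VAMP7, DHFRP1 and SNORD3C were the largest on the lower side at that mean. Without genes that had copies or could not be searched, 5 were higher and 10 lower. DHRSX and ZBED1 are still among the higher, and VAMP7 and RP11-48B14.1 among the lower. The search found no copy for any of them.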

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

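In this part, the sums over related genes were the tests chosen only after the results were seen. Of the 10788 genes compared, 2 were at least 2-fold higher with 1 siRNA and at least 2-fold lower with the other. One entry for U1, the spliceosomal small nuclear RNA (ENSG00000207205), had log2 ratios to control of -2.70 with siRNA 1 and 1.70 with siRNA 2, at 5.48 CPM in control, 0 with siRNA 1 and 20 with siRNA 2. UBE2Q2P3, a pseudogene of a ubiquitin-conjugating enzyme gene, had 1.13 and -2.94, at 8.24, 19.2 and 0.20 CPM. Each group had 1 library, so the difference was not tested. Both genes have near-identical copies, and all 12 distinct U1 entries together stood at 318, 436 and 325 CPM.

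Genes with the largest differences often stood near 0 in 1 library and far above 0 in another, as XAGE1C, DDT and SNORD3B-1 did. Of the 27 searched genes at least 4-fold apart in any pair of libraries, 70.4% had a near-identical copy of their first 50 bases (exact 95% interval 49.8% to 86.2%), against 14.3% of genes under 2-fold, so reads shared between near-identical copies may account for many of them. The interval treats genes as independent, although some, such as BOLA2 and BOLA2B, have identical values. RAB11A itself is among the 27, and VAMP7, DHRSX and ZBED1 are counted as having no copy. For genes 2-fold to 4-fold from control in both libraries the share was 18.2% (2 of 11, interval 2.3% to 51.8%), too few to decide. TRIM16 and TRIM16L moved in opposite ways with a sum of 27.0, 23.8 and 26.2 CPM. LINC00152 with AC068491.1 (35.4, 13.2 and 45.7 CPM) and the SNORD3 genes (3.44, 302 and 46.8 CPM) kept no steady sum. Nor did NSUN5 with NSUN5P2 (38.3, 21.4 and 17.2 CPM) or FAHD2A with FAHD2B (31.6, 45.8 and 28.7 CPM). A response of these loci to RAB11A siRNA stays open, as does the placement of reads in genes not searched, such as RBM8A, or in the pseudoautosomal VAMP7, DHRSX and ZBED1.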

How the results depend on the processing

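Tests chosen only after the results were seen were the counts with identical genes taken once and those without genes that had copies or could not be searched, and the places of list medians among matched lists under each setting. No paired analysis was possible because each group has 1 library. Of the recomputed answers to the comparisons, 69 stayed within their error or 1.5 times and 36 did not. Neither RAB11A log2 fold changed direction, and a reversal was not scored for the counts or the correlation. With a pseudocount of 5 CPM, which compresses ratios of low genes by construction, the RAB11A log2 fold, siRNA 1 against control, was -3.49 and the RAB11A log2 fold, siRNA 2 against control, was -2.34. With it siRNA 1 had 20 genes higher and 30 lower, siRNA 2 had 18 lower, 5 were higher in both, and the correlation was 0.67. With 0.5 CPM the correlation was 0.62. A minimum mean of 1 CPM tested more genes and gave 87 lower with siRNA 1, 49 with siRNA 2, 32 in both and 32 lower with siRNA 1 than siRNA 2. No filter gave 95, 54, 35 and 33. A minimum mean of 20 CPM tested fewer genes and gave 18 higher and 33 lower with siRNA 1, 8 and 13 with siRNA 2, 5 and 9 in both, 6 and 5 between siRNAs, and a correlation of 0.70. Taking identical genes once gave a correlation of 0.66. Leaving out genes with copies gave 21 higher with siRNA 1, 7 higher and 16 lower with siRNA 2, 2 and 11 in both, 5 and 10 between siRNAs, and a correlation of 0.67. Limma on both siRNA libraries against the control left 1 residual degree of freedom. Its counts lay more than 1.5 times from the 2-fold counts in both. Its only residual was the difference between the siRNAs. That does not measure spread of the control or between cultures, so its calls are not given. For named genes and lists, 2225 values stayed within their error, 107 did not, and 2 list medians whose 95% interval over members excluded 0 reversed: the RAB11 recycling median with siRNA 2 was 0.01 under TMM scaling and 0.01 under median-ratio scaling, which shift that ratio by 0.05. Another 19 of 416 list medians changed sign with an interval that spanned 0, so they carry no direction, among them receptor kinases with siRNA 2, interferon response with both siRNAs, heat shock with siRNA 1, ribosomal proteins with siRNA 2 and the respiratory chain with siRNA 2 without genes with copies (-0.07, 0.01 and -0.01). Of 10 lists outside the matched range with siRNA 1, 10 stayed outside under every setting, with siRNA 2 8 of 10 (not p53 and NF-kB) and between siRNAs 7 of 10 (not integrins, ribosomal proteins and small RNA pathway). Lists inside the range left it with siRNA 1 for integrins (0.14 at a minimum mean of 1 CPM and with no filter, 0.09 with a pseudocount of 5 CPM), ERK output (-0.18 at 20 CPM), the small RNA pathway (-0.29 at 20 CPM), and, without copies, receptor kinases (-0.25) and apoptosis regulators (0.12). Between siRNAs, interferon response left it at 1 CPM (0.22) and with no filter (0.18), p53 targets at 20 CPM (-0.20), and YAP/TAZ targets at 20 CPM (0.12) and without copies (0.11). The cause of the other changes was not tested. Both scalings left every 2-fold count within 1.5 times, as did requiring a binomial call in addition to a 2-fold ratio. Genes at 5 CPM rest on 125 tags, which sets the counting error there.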

Other observations

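Tests chosen only after the results were seen were the comparison of siRNA libraries that leaves out the control, the seed count among genes lower with siRNA 1 than siRNA 2, and the requirement added to the siRNA 2 seed test. Genes in the next paragraph were named after their values were seen, from those with no near-identical copy and a mean of at least 10 CPM.

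Single genes are given as values, with no replicate check and no test of a shared theme. KISS1, the kisspeptin gene, stood at 518 CPM in control, 1052 with siRNA 1 and 833 with siRNA 2 (log2 ratios 1.02 and 0.68). CD70, a TNF family ligand, had ratios of 1.11 and 0.79, SEMA7A, a membrane-anchored semaphorin, 1.23 and 0.82, and SERPINB7, a serpin, 1.20 and 0.79. AP1M2, a subunit of the epithelial clathrin adaptor that sorts cargo to the basolateral membrane, had ratios of 0.91 and 0.88. IDH1, the cytosolic isocitrate dehydrogenase, stood at 278, 109.7 and 167.7 CPM, PLIN2, a lipid droplet coat protein, at 144, 59.0 and 86.3, and NNMT, nicotinamide N-methyltransferase, at 27.6, 11.4 and 13.9. NUPR1, a stress-induced nuclear protein, stood at 392, 177 and 283 CPM. Some genes differed between the siRNAs. APOE, the lipid transport protein, stood at 55.1, 26.2 and 70.8 CPM, and GPNMB, a lysosomal glycoprotein, at 16.6, 9.20 and 20.1. ID3, an inhibitor of basic helix-loop-helix factors, stood at 19.2, 33.1 and 12.6 CPM, and TNFRSF11B, osteoprotegerin, had ratios to control of 0.55 and -0.52.

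With siRNA 1, G2/M and DNA replication lists lay above control. The unfolded protein response and ATF4 list, here the ATF4 list, and the NRF2 list lay below it. With siRNA 2 the NRF2 median of -0.07 lay inside the matched range. Between siRNA 1 and siRNA 2, which leaves out the control library, all 4 lists lay outside the range of matched random lists. Their medians there were 0.41, 0.19, -0.12 and -0.27, which speaks against a difference of the control library as the whole cause. The pattern was defined by siRNA 1, which is also in this ratio, and 10 of 26 lists lay outside between siRNAs. This result cannot tell a response to RAB11A siRNA from a shift of the single siRNA 1 culture. It speaks only to the part that differs between the siRNAs. The part common to both, such as the ATF4 list medians of -0.41 and -0.34, stays open to a difference of the single control library. Against GC content or transcript length bias, all 4 stayed outside the range with siRNA 1 after removing both trends, with 0.97 or more of their size kept. Both trends used the whole canonical transcript, so a bias from the sequence at the capped start that CAGE counts was not tested. A response to RAB11A loss and a difference in growth or density between the 3 cultures stay open and were not tested, because each group has 1 library.

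The siRNAs could also act on other transcripts through their seeds. For 3' UTR matches to the siRNA 1 guide seed (GATGGAA, 1404 of 9598 genes), the median log2 ratio of siRNA 1 to siRNA 2 was -0.014 with a site and 0.030 without, at percentile 0.0 of lists matched on expression and UTR length, and siRNA 1 to control was at percentile 0.0 as well. That is consistent with a small seed effect, yet of 20 genes at least 2-fold lower with siRNA 1 than siRNA 2, leaving out RAB11A itself, 9 had no canonical 3' UTR to search and 1 of the 10 searched had a site, so the seed leaves most of the large differences among searched genes unaccounted for. For the siRNA 2 seed (TTGCAGA, 1545 genes) the percentile was 2.24, below the 2.5 set beforehand. After that value was seen, siRNA 2 to control was also required to lie below 2.5, and at percentile 56.1 it did not, so no siRNA 2 seed effect could be decided.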
